A study of Arabidopsis thaliana with 4 samples.

How the data were processed

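RNA was measured by sequencing in germinating Arabidopsis thaliana seedlings of the Columbia wild type and of a line that overexpresses the zinc finger protein ZFP3 from an estradiol-inducible promoter (ZFP3ox). Per the labels, seeds were plated on 5 µM estradiol and harvested after 36 h, or on 5 µM estradiol with 2.5 µM abscisic acid (ABA, the hormone that holds back germination) and harvested after 84 h. The later harvest was chosen so that the seedlings had a radicle of similar stage, so ABA and time on the plate went together in every comparison of ABA with control. Per the labels, ribosomal RNA was depleted and reads of 50 bases were produced on a SOLiD instrument, which reads sequence as colours. There were 4 samples, 1 for each combination of genotype and treatment.

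The authors deposited 1 table of 23932 features with RPKM values (reads per kilobase of exon model, scaled to library size), which holds 2 columns for each sample. These are called column set 1 and column set 2 here. All values in the 8 columns were above 0, so genes without reads in some column may be missing from the deposited features. Neither labels nor headers say whether the sets came from separate seed batches, libraries or sequencing runs, so both columns of a sample were counted as 1 replicate and their log2 values were averaged. Per the authors' deposited settings, reads were matched in colour space and by strand, with at most 2 mismatches. A read that matched up to 10 places was still used, and values were made per gene. The program, the aligner, their versions and the genome build are not given in the sources used here, and neither is whether the settings cover both column sets. Since reads with several matches were used, values of closely related genes such as CAB1 and CAB2 or the Rubisco small subunits are uncertain for each single gene. The authors also deposited 4 tables of selected genes with a signed fold change, a score that is a ratio at or above 1, or minus the inverse of a ratio below 1. The deposited fold was within 2% of the mean of the ratios of both column sets for 92.7% to 100% of the genes, depending on table and comparison. The rule behind the selection is not given in the sources used here. In the tables of higher genes the lowest RPKM ratio in either column set was 1.895. In those of lower genes the highest was 0.619, so the listed genes were near 2-fold or beyond in each set.

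Depth was read from the low values. Each RPKM value was multiplied by the gene's exon length from the TAIR10.1 annotation, which was used for names and lengths only. In column set 1, 70.9% to 76.7% of the low values checked lay within 0.1 of a whole number of reads, against 20% with no steps. The step gave about 4.05 Mreads (M, mega) for wild-type control, 3.18 for wild-type ABA, 2.99 for ZFP3ox control and 2.61 for ZFP3ox ABA. In column set 2 the share was 22.2% to 25.7%, so the depth behind those columns is unknown. The sets also differed in scale: the median gene had 10.45 to 15.58 RPKM in set 1 and 3.26 to 4.19 in set 2, and the lowest 5% of genes reached 3.40 to 7.31 RPKM in set 1 but 0.42 to 0.60 in set 2. The raised floor of set 1 shrinks the ratios of weakly expressed genes in that set. No counting interval is given, since no file held read counts.

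Of the features, 23439 carried a locus code and a further 199 were matched by symbol and 252 by symbol and position to the reference. After 9 shared codes were set aside, 51 features had none. A gene was kept where at least 1 sample had 1 RPKM or more in both of its columns, which left 22646 genes. Values were log2(RPKM + 1), so ratios of genes near 1 RPKM are understated. Each comparison of 2 samples is a log2 ratio within a column set and the mean over both sets. With 1 sample per group it has no replicate check and no p-value. Genes are counted past a size rule of 2-fold in that mean, or 4-fold for the difference between the genotype ratios with and without ABA. For genes past the rule in both sets, the number for independent sets is given beside the count.

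The ABA effect averaged over genotypes and the genotype effect averaged over treatments were tested with limma 3.58.1 in R 4.3.3 on an additive model of the 4 samples. That model has 1 residual degree of freedom, which is the departure from additivity, and a prior of 6.70 degrees of freedom borrowed across genes. Adjusted p is Benjamini-Hochberg over 22646 genes, with a threshold of 0.05. These p-values therefore set an effect against that departure in these 4 samples and the borrowed prior. The departure also holds any real difference in ABA response between the genotypes. No spread between samples of the same group is measured, and nothing says that samples came from separate cultures. On simulated data for the averaged ABA effect, 100 of 100 genes changed 8-fold and 1 of 100 changed 2-fold were recovered, with 4 false calls. For ABA against control in wild type, 199 of 200 genes simulated 4-fold higher were at least 2-fold higher, and so were 96 unchanged genes. Unchanged genes at least 2-fold lower were not counted. On the higher side 186 changed and 24 unchanged genes passed in both sets. The simulated columns had independent noise centred on 0. The real ratios had medians of 0.31 and -0.03 in the sets, where independent sets would share 183 higher genes. The 24 may therefore understate how many unchanged genes pass in both real sets.

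Lists of genes were fixed before the data were examined. They are the ZFP subfamily, ABA receptors, ABA signalling phosphatases, ABA kinases and transcription factors, ABA-responsive markers, ABA metabolism, seed storage with oil body and LEA (late embryogenesis abundant) genes, reserve mobilisation, gibberellin, light signalling, photosynthesis and chlorophyll, flavonoid pathway, cell wall loosening, root hair cells, endosperm and seed coat, cell cycle, auxin, heat and protein stress, defence and jasmonate, reference genes and organelle-encoded genes. A list of nuclear rRNA genes had 0 measured members. Listed genes whose symbol and code did not match in the reference were dropped, 1 from heat and protein stress and 3 from reference genes. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe these samples and are not tests. In simulated data with independent genes 1 of 100 random lists of unchanged genes and 100 of 100 lists shifted by 1 log2 unit fell outside 2.5 to 97.5.

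The genes named were set by rule before the data were examined. They are ZFP3, the ABA markers ABI4, ABI5, RAB18 and RD29B, HY5 and chalcone synthase. For each averaged effect they include the 10 highest and 10 lowest by the smaller of both ratios, of the same sign, among genes with 5 RPKM or more. For each genotype comparison and for the difference between them they include the 5 highest and 5 lowest. In each list up to 4 members with the largest ratio were named. ABI3 and RD29A, which the rule also lists, were not analysed here. The test plan written before the data were examined allowed for read counts and, without them, for limma on log2 values, which is what was used. Alternatives were another scaling, other minima, size thresholds and pseudocounts, and, chosen after the data were seen, each column set alone, both sets required, a floor subtracted and all 8 columns fitted as libraries. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for everything outside limma.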

Results

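Transcript levels were compared between wild-type Arabidopsis and ZFP3ox seedlings, with and without ABA, in 4 samples: wild-type control, wild-type ABA, ZFP3ox control and ZFP3ox ABA, 1 of each. ZFP3 (AT5G25160), the C2H2 zinc finger gene driven by the inducible promoter, was high in both ZFP3ox samples and low in both wild-type samples. In column set 1 it had 8.66 RPKM in wild-type control, 15.66 in wild-type ABA, 175.59 in ZFP3ox control and 85.42 in ZFP3ox ABA. In column set 2 the values were 1.14, 1.01, 40.76 and 44.76 RPKM in the same order. The genotype labels therefore matched the level of the driven gene in all 8 columns. RAB18 (AT5G66400), a dehydrin gene used as a marker of ABA, was higher with ABA than without in both genotypes and both sets, with log2 ratios of 5.40 and 5.26 in wild type and 4.34 and 2.27 in ZFP3ox.

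**Figure D1:**
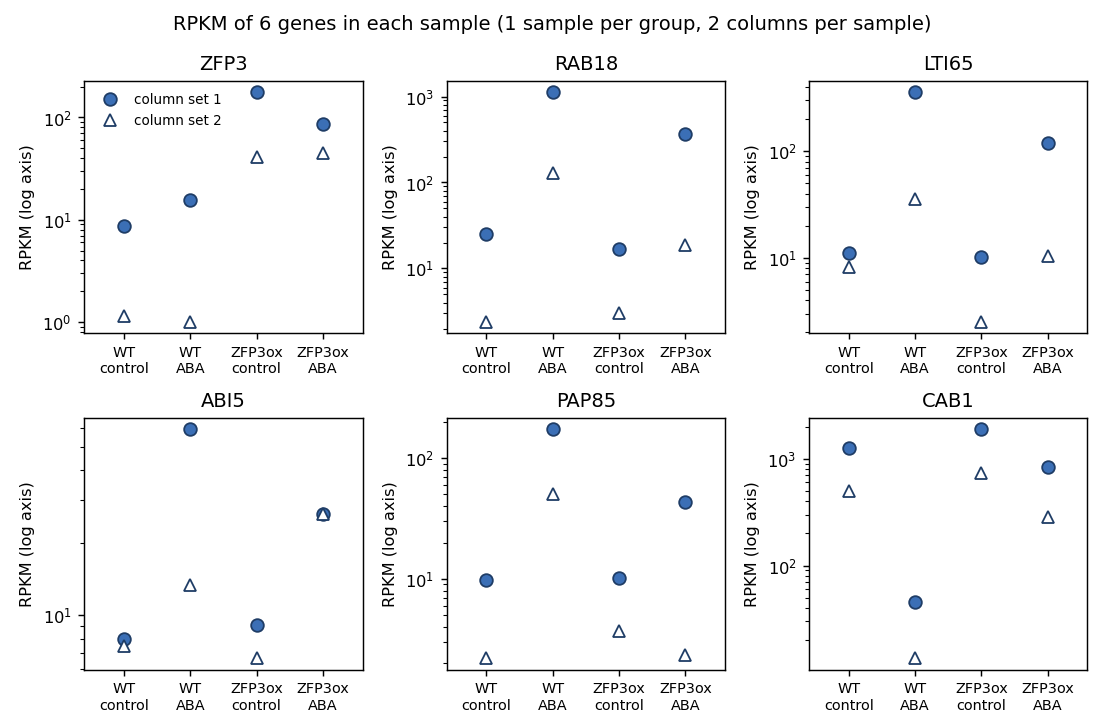
RPKM on a log axis of ZFP3, RAB18, LTI65 (RD29B), ABI5, PAP85 and CAB1 in each of the 4 samples (WT, wild type), with column set 1 as filled circles and column set 2 as open triangles and no error bars, since each group had 1 sample. ZFP3 was at 40.76 RPKM or more in the ZFP3ox columns and at 15.66 or less in the wild-type columns.

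The low values of column set 1 gave about 2.61 to 4.05 Mreads per sample (M, mega), while the depth of column set 2 is unknown. Across genes, both columns of the same sample correlated with Pearson's r of 0.504 to 0.640, below the 0.721 to 0.902 between different samples of the same set. Genes are not independent replicates, so these r values describe the columns. In set 1 the highest gene, AT2G01021, took 3.42% to 6.90% of the summed RPKM. In set 2 the highest gene was AT3G43990, with 18.1% to 28.7%. Ratios were therefore taken only within a set, and each is given below for set 1 and then set 2 where both matter.

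The first comparison asked what ZFP3 overexpression changed in the absence of ABA. ZFP3 itself stood apart from all other genes, with log2 ratios of 4.19 and 4.29. Next highest were AT1G30730 (1.62 and 2.84), AT4G36430, a peroxidase gene (2.14 in the mean of the sets), AT2G25169 (2.84 and 1.16) and PLIM2B, which encodes an actin-binding LIM protein (2.53 and 1.46). The lowest were AT2G26520 (-4.38 and -1.85), the transcription factor gene WRKY31 (-2.11 and -3.07), AT3G01060 (-3.27 and -1.76), the mitotic cyclin gene CYCB1;4 (-3.36 and -1.46) and AT5G09620 (-0.89 and -3.46). HY5, which encodes a bZIP factor of light-grown development, was lower in ZFP3ox in both sets without ABA (-0.67 and -0.82) and with ABA (-0.31 and -0.72). TT4, which encodes chalcone synthase at the entry to flavonoid synthesis, was higher in both (0.10 and 0.61 without ABA, 0.46 and 0.62 with it).

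Groups of genes moved little between the genotypes without ABA. In the photosynthesis and chlorophyll list 0 of 24 measured members passed the 2-fold rule and the median was 0.10. In the seed storage, oil body and LEA list 1 of 17 was lower, the albumin gene SESA1 (-0.39 and -2.46), and the list's median of -0.02 changed sign with the larger pseudocount. The reserve mobilisation list, genes that turn stored oil into sugar, had a median of -0.36 at percentile 0.15, with -0.54 and -0.22 in the sets, and 0 of 10 members past the rule. The lowest was MLS, malate synthase (-0.76 and -0.98). The flavonoid list had a median of 0.35 at percentile 99.9, although neither set alone lay outside the range of random lists, at percentiles 52.3 and 83.2. The root hair list had a median of -0.41 at percentile 0.46, with 16.6 in set 2, and the auxin list -0.26 at percentile 2.07, with 11.9 in set 1. The ABA metabolism list had a median of 0.23 at percentile 98.5 that turned between the sets (0.40 and -0.15, at percentiles 89.9 and 67.0). In it NCED4, a carotenoid dioxygenase gene, was higher in set 1 only (2.33 and -0.16). Among defence and jasmonate genes 1 of 9 was lower, ERF1 (-1.36 and -0.94), with a median of 0.03 whose sign depended on the scaling, and among light signalling genes 1 of 23, the early light-induced gene ELIP1 (-2.25 and -0.24).

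Across all genes, 216 were at least 2-fold higher and 357 lower in ZFP3ox without ABA. The balance turned round between the sets, with 1895 higher and 272 lower in set 1 alone and 242 higher and 2142 lower in set 2 alone. In both sets 31 were higher, where independent sets would share 20.3, and 41 lower, against 25.7. The ratios of the sets hardly correlated across genes, with r of 0.015. With 1 sample per group the difference has no replicate check, and the median ratio of all genes, 0.21 in set 1 and -0.20 in set 2, shows that the sets were centred differently.

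**Figure D2:**
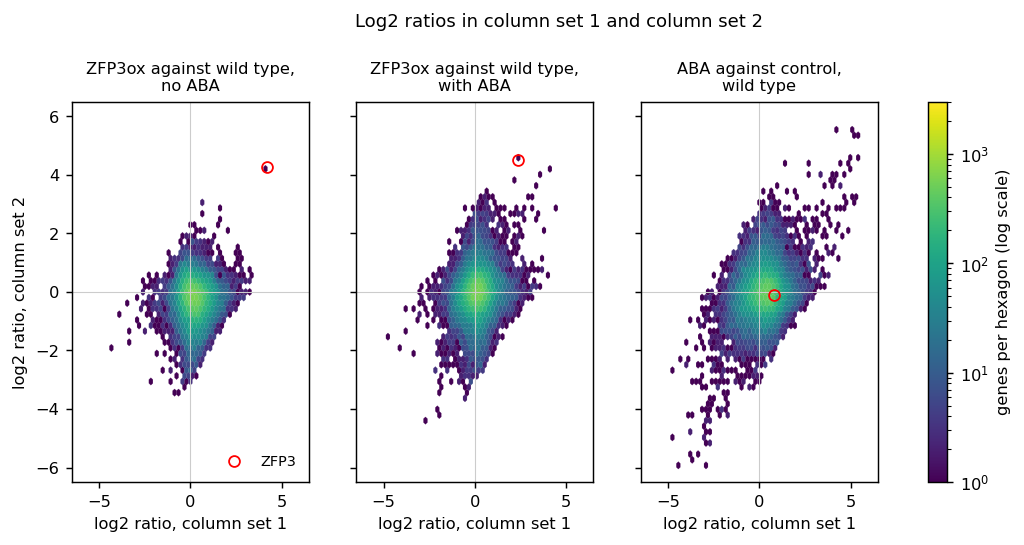
Log2 ratio of each of 22646 genes in column set 1 (x) against column set 2 (y) for ZFP3ox against wild type without ABA, ZFP3ox against wild type with ABA and ABA against control in wild type, with the colour giving the number of genes per hexagon on a log scale and ZFP3 circled in red. The correlation across genes was 0.015, 0.175 and 0.281 in these comparisons.

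With ABA present, ZFP3ox differed from wild type in genes of the photosynthetic apparatus. CAB1, which encodes a chlorophyll a/b-binding protein of the light-harvesting antenna, was higher in ZFP3ox by log2 ratios of 4.17 and 4.29, LHCB2.1 by 4.54 and 2.85, LHB1B2 by 3.50 and 3.98 and CAB2 by 3.45 and 3.65. CAB2 and LHB1B2 are LHCB1 genes and LHCB2.1 is an LHCB2 gene. Reads that matched several places were used, so the value of each single antenna gene is uncertain. Of the 24 measured members of the photosynthesis and chlorophyll list, 21 were at least 2-fold higher in ZFP3ox and 0 lower, 17 of them higher in both sets. The list's median was 2.05, with 2.33 in set 1 and 1.81 in set 2, above all random lists in each. Beyond the antenna, PSBO1 of photosystem II was higher by 3.19 and 2.85, and CHLH, a subunit of magnesium chelatase, by 2.48 and 0.56.

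Genes of seed reserves and of late embryogenesis were lower in ZFP3ox than in wild type with ABA. In that list 9 of 17 measured members were at least 2-fold lower and 0 higher, 8 of them lower in both sets. The median was -1.16, with -1.32 and -1.13, below all random lists. PAP85, a vicilin-like storage protein gene, had ratios of -1.97 and -3.94, the cruciferin gene CRC -2.26 and -2.64, CRA1 -2.15 and -1.70 and LEA4-5 -1.43 and -2.32. RAB18 was lower by -1.61 and -2.74 and LTI65, also known as RD29B, by -1.56 and -1.68. The transcription factor genes ABI4 (-0.64 and -0.80) and ABI5 (-1.15 and 0.93) did not pass the rule. The other lowest genes were AT1G73350 (-2.68 and -4.39), AT5G51370 (-1.84 and -4.22), AT3G02400 (-3.28 and -2.10) and AT2G26520 (-4.73 and -1.52).

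Other lists held fewer members past the rule. In the gibberellin list RGL2, a DELLA repressor of germination (-1.63 and -2.00), and GASA4 (-1.35 and -1.74) were lower among 19. The sign of the list's median of -0.01 depended on the scaling, while relative to all genes it lay between -0.085 and -0.046 throughout. SOM, a zinc finger gene that holds back light-dependent germination, was the only 1 of 23 light signalling genes past the rule (-1.39 and -1.79), in a list whose median was -0.21 at percentile 1.42. The glyoxylate cycle genes ICL (-1.22 and -1.37) and MLS (-1.56 and -1.87) were lower among 10 of reserve mobilisation, whose median of -0.54 lay at percentile 6.37. In cell wall loosening EXPA1 (-1.43 and -1.07) and EXPA3 (-0.70 and -1.35) were lower of 12, with a median of -0.44 at percentile 0.33, and 7.24 in set 1. The ABA-responsive markers split in the mean of the sets, with 3 higher and 3 lower of 18. Their median was 0.29 at percentile 98.7, with 69.5 in set 1. Past the rule in both sets were 0 on the higher side and 2 on the lower. P5CS1, the proline synthesis gene, was among the higher (1.33 and 0.91). The ABA metabolism list had a median of 0.42 at percentile 99.7, although neither set alone lay outside the range (0.44 and 0.18, at percentiles 97.3 and 91.0), and 0 of 12 past the rule, led by NCED5 (0.68 and 0.68). Of the ABA receptors PYL3 was higher (1.97 and 0.43) and PYR1 lower (-2.23 and 0.05), and of the kinases and transcription factors ABF4 was higher (0.46 and 1.65). In the flavonoid list LDOX was higher (1.87 and 0.74), in root hair cells PRP3 lower (-0.31 and -2.58) and in the cell cycle list MCM2 higher (-0.08 and 2.15). Organelle-encoded genes had a median of -0.77 at percentile 0.15, with -1.12 and -0.22 in the sets and percentile 28.9 in set 2.

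Over all genes 612 were higher and 460 lower in ZFP3ox with ABA. Set 1 alone had 1403 higher and 645 lower, and set 2 alone 1004 higher and 1395 lower. In both sets 143 were higher, against 62.2 for independent sets, and 114 lower, against 39.7. The split depended on the scaling: with median-of-ratios scaling 475 were higher and 577 lower. The median ratio of all genes was 0.14 in set 1 and -0.03 in set 2, and r between the sets was 0.175.

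The genotype effect was then averaged over both treatments and tested. ZFP3 rose by 3.84 on the log2 scale (standard error 0.27, adjusted p = 0.014 by limma), and AT2G26520 fell by 3.12 (adjusted p = 0.014 by limma). Both had the same direction in both treatments and both column sets. The agreement between treatments was fixed by the selection, since the residual of this test is the difference between their genotype ratios. With these settings 2 genes passed the threshold, while 1650 genes had an unadjusted p under 0.05 against 1132 by chance. The calls depended on the settings. With limma-trend ZFP3 passed and AT2G26520 did not (adjusted p = 0.0919), with median-of-ratios scaling 6 passed, both among them, and with a pseudocount of 5 the count was 0 (limma, 1667 with an unadjusted p under 0.05). ZFP3 did not pass in column set 1 alone (adjusted p = 0.234), and AT2G26520 did not in column set 2 alone (adjusted p = 0.804) or with 8 columns as libraries (adjusted p = 0.435). Genes with the next largest ratios in both treatments did not pass. NUDT22, a nudix hydrolase gene, had averaged ratios of 3.14 and 1.062 in the sets, and GRP-3, which encodes a glycine-rich cell wall protein, 1.495 and 1.34. DHAR1, dehydroascorbate reductase, had 0.62 and 1.97, AT4G09760 0.88 and 1.60, DAR5 1.198 and 1.75, AT2G32550 1.80 and 0.57, AT5G25250 (flotillin 1) 1.78 and 0.54 and CYP702A8 2.13 and 0.45. For DEG8 the ratio came from set 1 (2.38 and 0.0425). On the lower side BOB1, a chaperone gene, had -3.36 and -0.90, AT5G26260 -1.45 and -2.56, the tRNA isopentenyltransferase gene IPT2 -2.46 and -0.996, AT2G04520 -0.43 and -3.00 and the cysteine protease gene CP1 -1.51 and -1.29. AT5G58420 had -0.93 and -1.69, the dehydrin gene COR47 -0.64 and -1.78 and AT1G32560 (LEA4-1) -0.62 and -1.74, while AT1G31600 was low mainly in set 2 (-0.21 and -2.46). With the threshold adjusted over the list alone, 1 member rose in the ZFP subfamily, 1 rose and 2 fell among the ABA-responsive markers, 1 fell in reserve mobilisation and 1 in light signalling. In the other lists none passed, among them photosynthesis, storage and LEA genes. A gene with opposite values in the treatments also has a large residual in this model, which lowers the number of calls.

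The ABA comparison in wild type asked how 2.5 µM ABA, with the later harvest that went with it, changed transcripts. Seed reserve and desiccation genes were far higher with ABA. In the storage, oil body and LEA list 13 of 17 members were at least 2-fold higher and 0 lower, all 13 in both sets. The median was 3.13, with 3.46 and 2.80, above all random lists. LEA4-5 was higher by 4.32 and 5.55, the oleosin gene OLEO2 by 5.08 and 4.62 and GEA6 (EM6) by 4.66 and 4.04. LTI65 had 4.86 and 1.98, ABI5 2.75 and 0.76 and ABI4 1.59 and 1.004.

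Photosynthesis genes were lower with ABA in wild type in all 24 measured members, 23 of them in both sets, with a median of -3.35 and with -2.76 and -4.07 in the sets, below all random lists. LHCB2.1 had -4.48 and -5.88, LHCB3 -3.69 and -5.62 and PORB, which makes chlorophyllide in the light, -4.30 and -2.20. Of the ABA-responsive markers 5 of 18 were higher and 2 lower, with KIN1 at 3.89 and 1.35 and RD22 at -1.13 and -2.13 and a median of 0.19. The kinases and transcription factors had a median of 0.60 at percentile 99.8, and 90.9 in set 1, with 3 of 10 higher, and the phosphatases 0.39 with HAI3 higher (2.44 and 1.45). The receptors had a median of -0.17 at percentile 2.52 with none of 10 past the rule. In the gibberellin list 4 of 19 were higher, among them RGL2 (2.57 and 2.32), and 1 lower, with a median of 0.11 that lay at -0.04 relative to all genes. SOM was higher (3.09 and 2.86), as was MAN7, an endosperm mannanase gene (2.15 and 1.95). In the auxin list 3 of 12 were lower, among them GH3.3 (-2.25 and -1.22), with a median of -0.41 at percentile 0.16 that came from set 2 (0.14 and -1.08). The reserve mobilisation list had opposite medians in the sets, -0.42 and 1.29. In cell wall loosening 2 of 12 were higher and 2 lower, XTH4 among the latter (-2.20 and -2.56). PAL1, the first enzyme of the phenylpropanoid pathway, was lower among 16 flavonoid genes (-2.45 and -1.82). EXPA7 and EXPA18 were lower of 8 root hair genes, whose median was -0.19 at percentile 2.17, and 32.1 in set 2. In heat and protein stress DREB2A was higher (1.87 and 0.31) and HSP17.4 lower (-2.75 and -0.72), with a median of 0.29. The ZFP subfamily had a median of 0.44, defence and jasmonate 0.26, organelle-encoded genes 0.26, ABA metabolism 0.33 and cell cycle -0.12, all between percentiles 2.5 and 97.5. Among 6 reference genes 2 were lower with ABA, ACT2 (-1.13 and -0.87) and GAPC1 (-1.64 and -0.67), with a median of -0.62.

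Over all genes 1054 were higher and 647 lower with ABA in wild type, with 2773 and 1101 in set 1 alone and 1492 and 1331 in set 2 alone. In both sets 331 were higher, against 183 for independent sets, and 311 lower, against 64.7. The median ratio of all genes was 0.31 in set 1 and -0.03 in set 2. Scaled by median-of-ratios the split turned to 702 higher and 961 lower, and with organelle-encoded genes removed before scaling to 742 and 908. That removal took out 7 organelle-encoded features only, since 0 of the listed nuclear rRNA genes were measured. AT2G01021, the highest gene of set 1, stayed in.

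In ZFP3ox the storage and photosynthesis lists lay on the same sides with ABA as in wild type, with medians nearer to 0, a difference that was not tested. Of the storage, oil body and LEA list 9 of 17 were at least 2-fold higher and 0 lower, 7 in both sets, with a median of 1.204 and with 1.99 and 0.88 in the sets. Of the photosynthesis list 21 of 24 were lower, 7 in both sets, with a median of -1.42. Its median in set 1, -0.78, lay at percentile 13.7 and in set 2, -2.17, below all random lists. OLEO2 was higher by 2.52 and 5.96, LEA4-5 by 3.15 and 2.59 and PER1, a peroxiredoxin gene of dormant seeds, by 2.55 and 2.18, while RBCS3B was lower by -1.58 and -3.85. KIN1 was higher by 4.98 and 2.42, LTI65 by 3.42 and 1.69 and ABI5 by 1.43 and 1.84. The phosphatase list had a median of 0.72 at percentile 99.8, with ABI2 (1.14 and 1.77) and HAI1 (1.48 and 1.02) higher. The receptor list had a median of -0.46, below all random lists in the mean of the sets, although the only 1 of 10 members past the rule was higher, PYL3 (1.83 and 0.25). Of the ABA-responsive markers 7 of 18 were higher and 1 lower, and NCED3 (0.56 and 2.22) and NCED5 (0.60 and 1.46) were higher of 12 in ABA metabolism. In cell wall loosening 1 of 12 was higher and 4 lower, with a median of -0.39 at percentile 0.58, and 5.32 in set 1. GH3.3 was lower (-1.65 and -2.16). The auxin median of -0.01 changed sign with the larger pseudocount, though not relative to all genes (-0.22 and -0.12). The gibberellin, light signalling and flavonoid medians changed sign with median-of-ratios scaling and the endosperm median with the floor subtracted. Median-of-ratios scaling shifts all genes of a column alike. Relative to all genes, gibberellin had -0.100 before it and -0.107 after, light signalling -0.118 and -0.131 and flavonoid -0.066 and -0.073. Gibberellin turned to 0.027 with the larger pseudocount and flavonoid to 0.0009 with the floor subtracted. Organelle-encoded genes had a median of -0.63 at percentile 1.41, with 8.72 and 3.83 in the sets, and reference genes a median of -0.78. Over all genes 1031 were higher and 506 lower, with 1874 and 1243 in set 1 alone and 1812 and 547 in set 2 alone. In both sets 230 were higher, against 150 for independent sets, and 165 lower, against 30.0. The median ratio of all genes was 0.22 and 0.18 in the sets, and with median-of-ratios scaling 547 were higher and 923 lower.

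**Figure D3:**
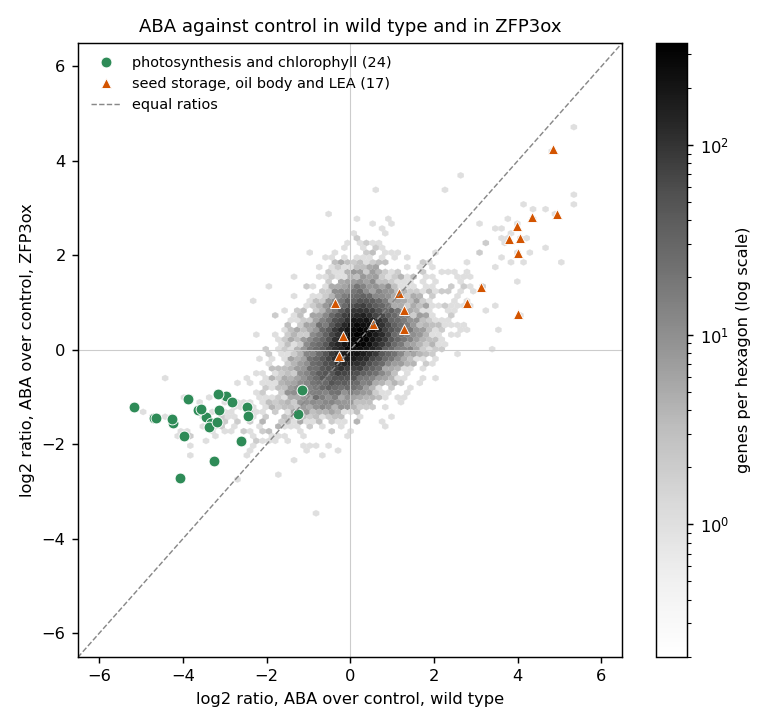
Log2 ratio of ABA over control in wild type (x) and in ZFP3ox (y), mean of both column sets, with 22646 genes as grey hexagons, 24 photosynthesis and chlorophyll genes as green circles, 17 seed storage, oil body and LEA genes as orange triangles and a dashed line at equal ratios. The median photosynthesis gene lay at -3.35 in wild type and -1.42 in ZFP3ox, and the median storage, oil body or LEA gene at 3.13 and 1.204.

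Averaged over both genotypes, 65 genes rose and 82 fell with ABA (limma, adjusted p under the threshold). All 147 had the same direction in both genotypes and both sets. The agreement between genotypes was fixed by the selection, since the residual of this test is the difference between their ABA ratios. It is no separate support. The count depended on the settings, with 2 genes for a pseudocount of 5, 6 from set 2 alone, 104 from set 1 alone and 661 with median-of-ratios scaling. AT3G02480, a LEA gene, rose by 4.99 (standard error 0.25; adjusted p = 0.0016) and OLEO2 by 4.54 (adjusted p = 0.0018). RAB18 rose by 4.32, AT3G15670 by 4.18, LEA4-5 by 3.90, AT3G17520 by 3.78, AT1G04560 by 3.71, LEA18 by 3.66, GEA6 by 3.58 and AT5G35660 by 3.298, with adjusted p from 0.016 to 0.0209. LTI65 rose by 2.99 and ABI5 by 1.70 (adjusted p = 0.0333), while ABI4, with a mean of 0.79, did not pass. Among the genes that fell, RBCS3B fell by 3.39, RCA (Rubisco activase) by 3.05, DRT112 (plastocyanin) by 2.94, PORB by 2.80 and GER3, a germin gene, by 2.76. GRP3S fell by 2.39, UCC2 by 2.31, AT3G14415 (a glycolate oxidase of photorespiration) by 2.27, FBA2 (plastid aldolase) by 2.21 and PRK (phosphoribulokinase of the Calvin cycle) by 2.09, with adjusted p from 0.016 to 0.0316 over these 10 genes.

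By list, 8 of 24 photosynthesis genes fell over all genes tested, and 24 of 24 adjusted over the list alone. In storage, oil body and LEA 7 of 17 rose over all genes and 13 adjusted over the list alone. Of the ABA-responsive markers 4 rose over all genes, RAB18, LTI65, KIN1 and ADH1, and adjusted over the list alone 5 rose and 2 fell. In cell wall loosening XTH4 and XTH31 fell over all genes, with 2 higher and 3 lower adjusted over the list alone. In the auxin list GH3.3 fell, with 3 lower adjusted over the list alone, and among kinases and transcription factors ABI5 rose, with 2 higher. In the other lists none passed over all genes. Adjusted over the list alone 2 phosphatase genes rose, in the flavonoid list 2 rose and 2 fell, in light signalling 1 rose and 2 fell and 2 reference genes fell. In the same way 1 rose in each of the ZFP subfamily, gibberellin, endosperm and defence lists, and 1 fell in heat and protein stress. Over all genes 4316 had an unadjusted p under 0.05 against 1132 by chance. Scaled by median-of-ratios the split of the calls was 147 higher and 514 lower.

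**Figure D4:**
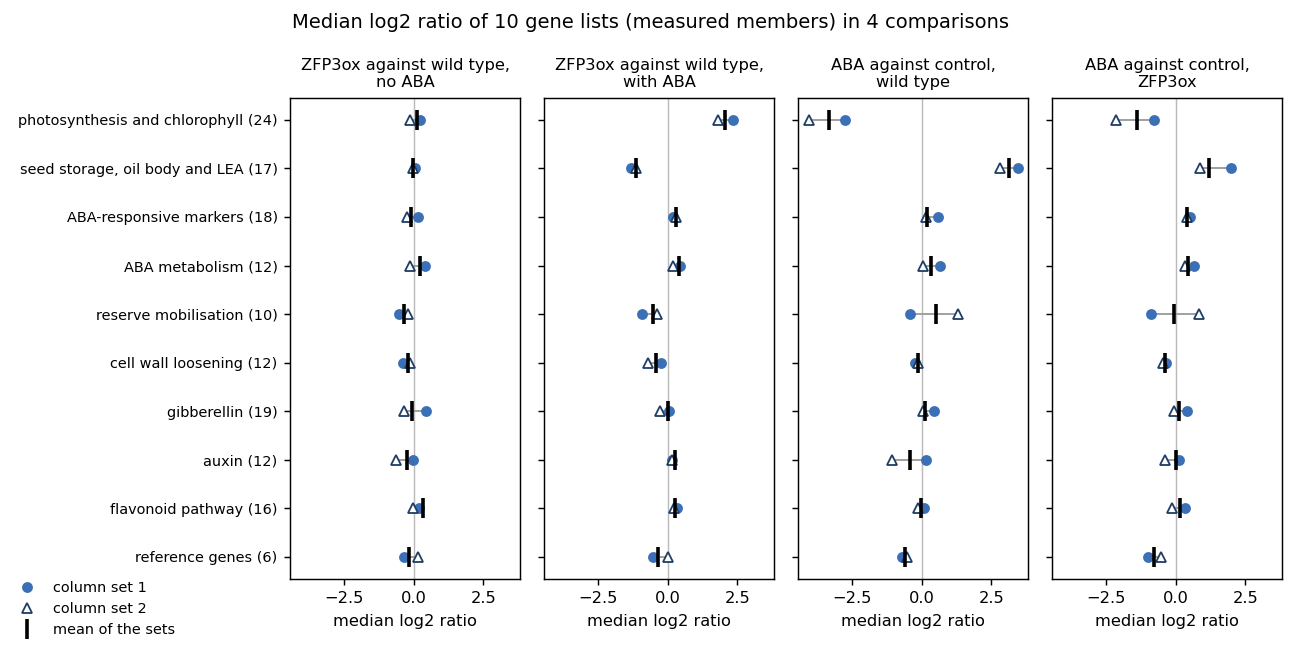
Median log2 ratio of 10 gene lists (number of measured members in brackets) in the 4 comparisons between samples, for column set 1 (filled circles), column set 2 (open triangles) and the mean of the sets (black bars). The photosynthesis list had medians of 0.10, 2.05, -3.35 and -1.42 from left to right, and the storage, oil body and LEA list -0.02, -1.16, 3.13 and 1.204, where the value of -0.02 changed sign with the larger pseudocount.

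The genotype ratio with ABA was set against that without. LHCB2.1 had the largest positive difference among the genes of the naming rule, 4.60 and 3.31 in the sets, followed by LHB1B2 (3.02 and 4.54), CAB1 (3.59 and 3.71), AT3G24130 (3.50 and 3.28) and AT3G01060 (3.25 and 3.44). The most negative were AT1G73350 (-2.60 and -4.30), PAP85 (-2.01 and -4.50), AT5G51370 (-2.55 and -3.71), AT3G54940, a papain-like protease gene (-2.10 and -4.16), and AT2G40800 (-2.47 and -2.94). In the photosynthesis list 11 of 24 differences were at least 4-fold positive, 6 in both sets, with a median of 1.93. In storage, oil body and LEA 2 of 17 were negative, with a median of -1.37. The 7 organelle-encoded genes had a median of -1.08, below all random lists in the mean of the sets. In the sets alone it lay at percentiles 0.87 and 2.17, and 0 of the 7 passed the 4-fold rule. Over all genes 76 differences were at least 4-fold positive and 42 negative, with 142 and 234 in set 1 alone and 574 and 210 in set 2 alone. In both sets there were 23 positive, against 3.60 for independent sets, and 11 negative, against 2.17. In the model of 4 samples no residual degrees of freedom remained for a test of these differences.

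Whether genes that responded to ABA also differed between the genotypes was examined across genes. The genotype effect averaged over treatments and the ABA effect averaged over genotypes share no noise when the columns vary alike, and correlated with r of 0.060 and Spearman's rho of 0.162, against a simulated r of 0.018 with no effects. The covariance was 0.0098, against 0.0013 simulated. The sets differed, with r of 0.325 within set 1 and -0.108 within set 2. Across sets r was -0.013 and -0.0996, and for genes with 5 RPKM or more 0.0024, so no direction held for the relation of genotype effect and ABA effect. Without ABA, the genotype ratio and the ABA ratio in wild type share the wild-type control. Their r was 0.406, against 0.502 simulated with no effects, and their covariance 0.099, against 0.071 simulated. Taking the first from one set and the second from the other gave r of 0.042 and -0.047. Of the genes lower in ZFP3ox with ABA, 283 were higher with ABA in wild type, where independent lists would share 21.4. A simulation with no effects shared 3, but its lists were shorter. With noise of that size 96 unchanged genes were at least 2-fold higher with ABA in wild type, while the real list held 1054. The simulated number therefore does not show how much a shared sample adds. The genotype ratio with ABA and the ABA ratio in wild type share the wild-type ABA sample. Taken across sets the overlaps were 168, against 42.5, and 270, against 171, so part of the excess may come from the shared sample. The ABA ratios in wild type and in ZFP3ox share no sample and correlated with r of 0.451, covariance 0.142. Of the higher genes 163 were shared, against 48.0 for independent lists, and of the lower genes 225, against 14.5. Taken across sets r was 0.279 and 0.109, with 306 higher genes shared, against 222, and 164, against 123, and with 200 lower genes, against 26.6, and 188, against 73.1. Of such relations 35 were computed, and genes are not independent replicates.

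The authors' deposited tables list 803 genes as higher and 543 as lower with ABA, and 225 as higher and 165 as lower in ZFP3ox. The ZFP3ox tables hold for the comparison without ABA: with ABA the deposited fold was negative for 71 of the 225 and positive for 104 of the 165. Of the genes listed as higher in ZFP3ox 149 were kept here and 75 passed the size rule. Of those listed as lower 142 were kept and 94 passed. The ratios here hold a pseudocount of 1 RPKM and the deposited fold does not, which lowers the counts here. In the authors' deposited table of genes higher with ABA the median fold was 2.93 in wild type, 1.59 in ZFP3ox and -1.32 for ZFP3ox against wild type with ABA. In the authors' deposited table of genes lower with ABA these medians were -2.78, -1.69 and 1.39. Of the genes kept here, the table of genes higher with ABA and that of genes higher in ZFP3ox shared 41, against 4.65 for independent lists. The tables of lower genes also shared 41, against 3.28. The tables of opposite direction shared 3 and 1. These tables were chosen by the authors on the same columns and share the wild-type control, so the overlaps are not independent evidence, and part of the excess may come from that control. By the size rule here 51 genes were higher in both contrasts, against 10.1 for independent lists and 8 simulated with no effects. Lower in both were 115, against 10.2 and 14. The simulated lists were shorter than the real ones, so 8 and 14 do not show how much the shared control adds.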

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

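The tests of the floor of column set 1 and of mixed samples in the photosynthesis and storage pattern, and of the correlation across sets in the pattern shared with ABA, were chosen after the values they rest on had been seen. The other tests were written before their values were known. Of 64 genes named by rule, 9 were flagged. In these a ratio had opposite signs without and with ABA, or in wild type and in ZFP3ox, in both column sets. Some of the 64 were named for a large difference between the genotype ratios and others for equal signs. Whether a gene was flagged therefore depended in part on the naming rule, and the opposite signs are no separate support. With 1 sample per group these differences were not tested between samples. A limma fit of the 8 columns as libraries was chosen after the data were seen. It treats the columns of 1 sample as replicates, so it cannot decide on these differences.

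The photosynthesis antenna gene LHCB2.1 had a genotype ratio of -0.26 without ABA and 3.69 with it, a difference of 3.9549. WRKY31 differed by 3.3022, with genotype ratios of -2.59 without ABA and 0.71 with it, and equally by 3.3022 when read as the ABA ratio in wild type (-2.31) and in ZFP3ox (0.996). AT3G01060 had ABA ratios of -2.02 in wild type and 1.33 in ZFP3ox, a difference of 3.3469. AT3G24130, with -0.56 and 2.83, differed by 3.3899. AT4G36430, with 0.47 and -0.66, differed by -1.1257. The storage protein gene PAP85 had genotype ratios of 0.30 without ABA and -2.95 with it, a difference of -3.2548. The protease gene AT3G54940, with 0.46 and -2.67, differed by -3.1296, and AT2G40800, with 1.45 and -1.26, by -2.7095. The glycolate oxidase gene AT3G14415, with -0.34 and 0.30, differed by 0.6359.

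The pattern a biologist would want to follow first is that photosynthesis genes were higher and seed storage, oil body and LEA genes lower in ZFP3ox than in wild type with ABA. The floor of column set 1 does not account for it, since in column set 2 alone the medians of these lists were 1.81 and -1.13. RNA of control seedlings mixed into the ZFP3ox ABA sample stays open: if the unmixed part had the wild-type ABA levels, which is assumed, the median share needed in column set 2 was 18.22% for 22 photosynthesis genes (quartiles 15.1% and 25.5%) and 77.7% for 13 storage genes (59.2% and 84.9%). In column set 1 the ranges overlapped, at 42.4% to 67.0% and 65.3% to 78.8%, so unequal shares were not found in both sets. With 1 sample per group the genotype, a mixed sample and a difference between single samples cannot be told apart.

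A further pattern is that genes higher or lower in ZFP3ox without ABA moved the same way with ABA in wild type, where both contrasts are taken against the same wild-type control columns. Genes past the size rule in both contrasts within a set numbered 795 and 83 on the higher side, and 6 passed in both sets, 2.06 times the number for independent sets. On the lower side 12 of 153 and 625 passed in both, 2.84 times that number. These ratios lie between the limits set for and against the shared control. Correlations taken across the sets were 0.042 and -0.047, but the poor repeat of the genotype ratios allows at most 0.065, so the shared control and a shared response cannot be told apart.

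The genotype ratios without ABA hardly repeated between the column sets. Few reads behind weakly expressed genes do not account for it, since r was 0.0066 in the 4530 genes of highest mean value, where it was 0.306 for the genotype ratios with ABA and 0.455 for the ABA ratios in wild type. For the floor of column set 1 the test cannot decide. With the 5th percentile of each column subtracted r rose from 0.015 to 0.048, under the limit of 0.1 set beforehand. The same step lowered r from 0.175 to 0.139 for the genotype ratios with ABA. For the ABA ratios in wild type it fell from 0.281 to 0.255, so a low r after subtraction does not exclude the floor. A difference between the genotypes confined to few genes at this stage stays open and was not tested.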

How the results depend on the processing

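Each column set alone, both sets required, the subtracted floor, the fit of 8 columns, correlations across sets and the other scalings of the correlation and list medians were chosen after the data were seen. With 1 sample per group, and reads known only for column set 1 at 2.61 to 4.05 Mreads (M, mega), weakly expressed genes carry few reads and no value here separates the sample from its group. Replicates could not be paired because each group held 1 sample. The additive model compares the genotypes within treatments, and the fit of 8 columns had the column set as a term. Tests on read counts were not run, since the values are RPKM, and neither were uniquely mapped reads, for which no column was used here. Scaling to totals is what the deposited RPKM already holds. Of 88 main values under alternatives 36 stayed near the reported one and 52 did not. Near means within 1.5 times, or for the correlation of the averaged effects within its sampling interval for independent genes. The cause was not tested unless the setting itself gives it.

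The values below are for ZFP3ox against wild type without ABA, the same with ABA, ABA in wild type, ABA in ZFP3ox and the difference of the genotype ratios, in that order, where 573, 1072, 1701, 1537 and 118 genes passed the size rule. A 1.5-fold rule gave 3058, 4148, 5625, 5910 and 1204 and a 3-fold rule 66, 216, 454, 253 and 10, by construction. A pseudocount of 5, which shrinks ratios of weak genes, gave 206, 479, 799, 609 and 39. Column set 1 alone gave 2167, 2048, 3874, 3117 and 376, and column set 2 alone 2384, 2399, 2823, 2359 and 784. Requiring both sets gave 72, 257, 642, 395 and 34. Subtracting the 5th percentile of each column gave 1754, 2629, 3091, 3188 and 496.

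The averaged ABA effect, with 147 genes by limma, gave 661 with median-of-ratios scaling, 2 with a pseudocount of 5, 6 from column set 2 alone and 258 with 8 columns as libraries. Its other settings gave 104 to 178. The averaged genotype effect, with 2 genes, gave 1 with limma-trend, 6 with median-of-ratios scaling, 0 with a pseudocount of 5 (limma, 1667 genes with an unadjusted p under 0.05), 1 from column set 1 alone and 1 from column set 2 alone. The correlation of the averaged effects, 0.060, became 0.0024 for genes with 5 RPKM or more, 0.406 for ABA in wild type and -0.189 for ABA in ZFP3ox against the genotype ratio without ABA, where each pair shares a control sample. It was 0.325 in column set 1, -0.108 in column set 2, and -0.013 and -0.0996 across sets. Of 84 list medians 24 lay outside the range of random lists, and 9 did so on the same side in both sets. With independent genes and comparisons 4.2 would lie outside it. Genes of a list need not be independent and the comparisons share samples, so 4.2 may understate chance.

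Of 130 ratios of named genes 113 were past the size rule. Of these 0 changed sign under median-of-ratios scaling, removal of organelle-encoded genes, a pseudocount of 5, the subtracted floor or column set 1 alone. Genes named for the size of their ratio in the mean of the sets are among them, so the steady signs are no separate support. In column set 2 alone 2 changed sign, CYP702A8 without ABA, at -0.23, and DEG8 with ABA, at -0.042. Among ratios short of the rule, that of ABI5 without ABA, 0.012, changed sign under both scalings, the subtracted floor and column set 2 alone, and in all 8 of the 130 changed sign in column set 2 alone. The others were ABI5 with ABA, ABI4 and RAB18 without ABA and both ABA ratios of ZFP3.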

Other observations

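Gene Ontology terms carried by the deposited table were looked at after the values had been seen, so the medians below are hypotheses. For 413 terms, whose genes need not be independent, the median log2 ratio was taken relative to all genes. With independent genes chance would put 20.7 outside the range of random lists in each comparison. Outside it in the mean lay 36 terms for ZFP3ox against wild type without ABA, 43 with ABA, 71 for ABA in wild type, 63 for ABA in ZFP3ox and 37 for the difference between the genotype ratios, and outside on the same side in both sets lay 2, 10, 20, 17 and 9. With ABA, the 102 genes of ribosome biogenesis had a median of -0.50 in ZFP3ox against wild type (-0.77 and -0.22 in the sets) and the 180 genes of protein folding -0.19 (-0.30 and -0.13). The 12 genes of negative regulation of seed germination had -0.65 (-1.06 and -0.67). On the higher side, beside 65 photosynthesis genes at 0.83, were 30 genes of the response to blue light at 0.32 and 65 genes of lipid transport at 0.21. The difference between the genotype ratios with and without ABA was negative for the 35 genes of translational elongation, at -0.69 (-0.38 and -0.88), and positive for the 33 genes of the response to far red light, at 0.34 (0.41 and 0.62).

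For ABA in wild type the terms picked here with lower medians were 43 glycolysis genes at -0.54, 52 of fatty acid biosynthesis at -0.38, 16 of microtubule-based process at -0.68, 16 of cellular glucan metabolism at -0.78 and 23 of chlorophyll biosynthesis at -0.99. Terms picked with higher medians were 15 genes of lipid storage at 0.73 and 14 of starch breakdown at 0.34. In ZFP3ox the 53 genes of nucleosome assembly had -0.55 (-0.82 and -0.22), the 15 genes of the tricarboxylic acid cycle -0.66 and the 278 genes of the response to cadmium -0.58. In ZFP3ox and wild type alike the 217 genes of the response to cold lay low, at -0.35 and -0.29. No replicate stands behind these medians, and harvest time went with ABA.

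With all 8 columns fitted as libraries by limma, an alternative chosen after the data were seen, 1 gene passed for ZFP3ox against wild type with ABA, CAB1 (adjusted p = 0.0033), and 72 rose and 97 fell with ABA in wild type, RAB18 among them (adjusted p = 0.0017). By limma 0 passed for ZFP3ox against wild type without ABA (611 with an unadjusted p under 0.05), where ZFP3 had an adjusted p of 0.0697, 0 for ABA in ZFP3ox (1792) and 0 for the difference between the genotype ratios with and without ABA (573). The columns of a sample need not be separate cultures, so that fit may hold no spread between cultures. Its p-values describe these columns and are no test of genotype or ABA. Its residual holds the differences between the sets that vary with the sample. The counts of 611 and 573 lie under the 1132 genes that chance would give. For these comparisons the fit was strict, so its 0 calls say little.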
